A study of Mus musculus with 4 samples.

How the data were processed

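RNA was measured in MC38 murine colon adenocarcinoma cells on the Clariom S mouse array, a 1-colour oligonucleotide array that reads 1 summarised signal per probe set. Per the labels' protocols, total RNA was taken up with a column kit, amplified to cRNA, copied into single-stranded cDNA, fragmented and labelled with biotin. The 4 arrays, 1 per sample, hold untransfected cells (WT), cells with an empty vector (MOCK), and a pair of knockout clones of Mgat5 (clone 1 and clone 2). Per the submitters' processing notes, the authors used the Transcriptome Analysis Console, whose version is not given in the sources used here. The deposited values are normalized log2 signals, 1 per feature and array, and the log2 scale was read from their range. The method of normalization and summarisation, any filter on features, and the genome build behind the array annotation are not given in the sources used here. No scanner files were used here, so background correction was not repeated.

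Groups came from the sample titles, with MOCK and WT as the control group and both clones as the knockout group, 2 arrays in each. A cell-type label on all 4 samples names the knockout, the controls included, so the titles and the design text were followed instead. Each column of the table matched 1 sample, and 0 columns were left without a sample. No labels say whether the arrays came from separate cultures or from more than 1 batch.

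The table held 28846 features. The 6640 control features, recognised by the start of their identifiers, were left out, and 22206 probe sets were tested with no filter on dim signal. Gene names came from the platform's annotation table, and symbols were set to those of the RefSeq gene table of assembly GRCm38.p6 through the Entrez identifier, which matched 19572 probe sets and changed 0 symbols. Exactly 1 symbol was found for 19572 probe sets, several for 0 and none for 2634. The named probe sets stand for 19505 genes. Where a gene had more than 1 probe set, the one with the highest mean over all 4 arrays stood for it. The RefSeq table was used only for names and for which genes neighbour each other on a chromosome, and no coordinates are given because the array's own build is not stated.

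The main test was limma (version 3.58.1, under R 4.3.3), with lmFit and eBayes on the log2 values as deposited, knockout minus control, and no covariate. P-values were adjusted by the Benjamini-Hochberg method over all 22206 probe sets, and a probe set was called at an adjusted p under 0.05. Standard errors are the moderated ones of that fit. Values of a group are given as mean ± SD with n = 2. With 2 arrays per group their number limits the precision.

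A set of 37 gene lists was fixed before the data were examined, for glycosylation, immune recognition, adhesion, signalling, growth, metabolism, markers of other cell types and RNA quality. Lists were tested with limma's camera at its preset correlation between genes of 0.01, which asks whether a list's genes shift relative to all other genes. The tests were repeated with a correlation estimated per list, and with fry, which asks whether a list's genes move 1 way on balance. Adjustment ran over the 37 lists. Beside each list, the number of members past an adjusted p of 0.05 was counted over all genes and again adjusted over the list alone. For single clones, which have no replicates, a list's median difference from the mean of the controls was placed as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. Random lists do not keep the correlation between a list's genes, so extreme percentiles arise between controls too. For MOCK minus WT, as deposited, mitosis stood at percentile 100 and immediate early genes at 0.

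Differences between the clones, and between MOCK and WT, rest on single arrays and have no test. They are given as numbers of probe sets at least 1 log2 unit apart. The number of probe sets whose lowest value in 1 group lay at least 1 log2 unit above the highest value of the other was counted for the knockout against control and for the other ways to split the 4 arrays into pairs.

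The genes named in the text were chosen by a rule written before the data were examined. It takes Mgat5, then per direction the 12 genes with the largest difference among those called with both clones on 1 side of both controls. Where fewer were called, it fills up to 12 with the genes with the widest gap between the groups, which are given as values. From each list it takes up to 4 members with the largest difference and any called member, and between the clones and between the controls the 6 genes per direction with the largest difference. Predicted and clone-named genes were passed over. Genes outside this rule are said to be so where they appear.

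The alternatives were quantile normalization of the deposited values, centring of each array on its median, filters at the median and the 25th percentile of mean signal, eBayes with trend and robust, an ordinary linear model without moderation, 1 probe set per named gene, an adjusted p under 0.1, an unadjusted p under 0.05 with at least a 2-fold difference, a gap of at least 1.5-fold, and each array left out in turn. Combinations of these, and the lists without the genes from Chmp5 to Alg2, were added after the data were seen. With 1 array left out, its group holds a lone array that is assumed to vary like the other group. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

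The fits were tested on simulated data, with 4 arrays drawn around the 22206 real means and residual variances drawn from the fitted prior, and 40 probe sets changed by each known amount in each of 20 runs. For the knockout against control, the simulated fit called 39.8% of the probe sets changed 4-fold, 92.8% of those changed 8-fold, 99.5% of those changed 16-fold and 99.9% of those changed 32-fold, and 0.6% of those changed 2-fold. The median of 7 false calls per run came beside the calls of all these changed probe sets. It is not a number to set against the calls of the real fit, which may hold fewer changed probe sets. The shares called depend on these changed probe sets too, since more of them loosen the cutoff after adjustment. Variances were also drawn without regard to signal, while eBayes with trend and robust moved the real calls from 9 to 340. The shares called therefore need not hold for the real fit. A simulated list of 36 genes shifted by 0.5 log2 units had an unadjusted camera p under 0.05 in 20 of 20 runs with the preset correlation and in 15 with an estimated one, and an unshifted list in 0 runs with either. The simulated genes varied independently of each other, whereas the estimated correlation of the real interferon list was 0.832. The runs therefore do not show how often camera at the preset correlation would call an unshifted list of correlated genes.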

Results

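Gene expression was compared between MC38 cells, a mouse colon adenocarcinoma line, with and without a CRISPR-Cas9 knockout of Mgat5. Mgat5 encodes N-acetylglucosaminyltransferase V, the Golgi enzyme that adds the beta-1,6 branch to N-glycans. The knockout group held clone 1 and clone 2, and the control group held untransfected cells (WT) and cells with an empty vector (MOCK), with n = 2 arrays per group. The series asks how the expression profile of the knockout cells differs from that of the controls. The arrays did not share 1 distribution. The 75th percentile of the 22206 probe sets was 9.26 log2 units in MOCK, 9.39 in clone 1, 9.60 in clone 2 and 8.87 in WT, and the 99th percentile was 15.9, 15.8, 15.8 and 14.7 in the same order. The Pearson correlation across probe sets, which are not independent replicates, ran from 0.976 between clone 2 and WT to 0.989 between MOCK and WT. The median over all probe sets of the difference, knockout minus control, was 0.18 log2 units, and -0.02 after quantile normalization, so differences should be read against that shift. The median of the features whose identifiers mark them as negative controls was 5.22 in MOCK, 5.16 in clone 1, 5.20 in clone 2 and 5.12 in WT, and for genes below that level in a group the signals are given in place of a fold or a difference. The 75th percentile of these features ran from 6.29 in WT to 6.56 in MOCK, so a fold for a gene with signals between these levels may still rest on background. P-values here measure the spread between these 4 arrays only. Both knockout arrays are titled as clones and neither control is, so differences that come with cloning cannot be told apart from effects of Mgat5 loss.

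Mgat5 itself was lower in both clones than in both controls. Its log2 signal was 8.19 in MOCK and 8.27 in WT, a mean of 8.23 ± 0.06 (SD, n = 2), against 7.46 in clone 1 and 7.57 in clone 2, a mean of 7.52 ± 0.08 (SD, n = 2). The knockout mean was 1.64-fold lower, which did not pass the limma test (SE 0.37, adjusted p = 0.631, and 0.419 to 1 over the alternatives). The order of the arrays goes with the sample titles. A guide-directed cut can leave the transcript in place, and where the probes lie relative to the cut is not given in the sources used here, so the level checks the labels only in part.

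Clu, which encodes the secreted chaperone clusterin, rose 36.2-fold in the knockout, from 8.23 ± 0.14 to 13.41 ± 0.45 log2 units (SD, n = 2 per group, SE 0.40, limma adjusted p = 0.00179). Zfp981 rose from 4.87 in MOCK and 4.85 in WT, below the median of the negative controls, to 8.50 in clone 1 and 10.37 in clone 2 (SE 0.55, adjusted p = 0.0248). Zfp980 rose 14.0-fold (SE 0.49, adjusted p = 0.0334), Zfp600 12.2-fold (SE 0.44, adjusted p = 0.0248) and Rex2 8.45-fold (SE 0.41, adjusted p = 0.0423), and these and Zfp981 encode zinc finger proteins and lie close together on chromosome 4. Fam180a rose 11.3-fold (SE 0.38, adjusted p = 0.0201). Gfra2, a co-receptor for the growth factor neurturin, was the single called gene that fell, from 9.26 in MOCK and 11.38 in WT to 4.84 in clone 1 and 4.65 in clone 2, below the median of the negative controls (SE 0.59, adjusted p = 0.0201). The called probe sets numbered 9, with 8 higher and 1 lower, and included the predicted gene Gm5169, outside the naming rule, at 7.71-fold higher, and 1 probe set with no gene name. After quantile normalization Clu alone was called. Zfp600, Fam180a and Rex2 lost the call, while their differences stayed near those as deposited, at 3.16, 3.05 and 2.63 log2 units. Zfp981 and Gfra2 lost the call too, and no difference is given for them because a group lay below the median of the negative controls. Over the alternatives the adjusted p of Clu ran from 5.65e-19 to 0.713. Without the WT array limma called 0 probe sets, with 832 at an unadjusted p under 0.05 against 1944 in all 4 arrays, without MOCK it called 1, which was Gfra2, and without clone 2 and clone 1 it called 149 and 529.

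**Figure D1:**
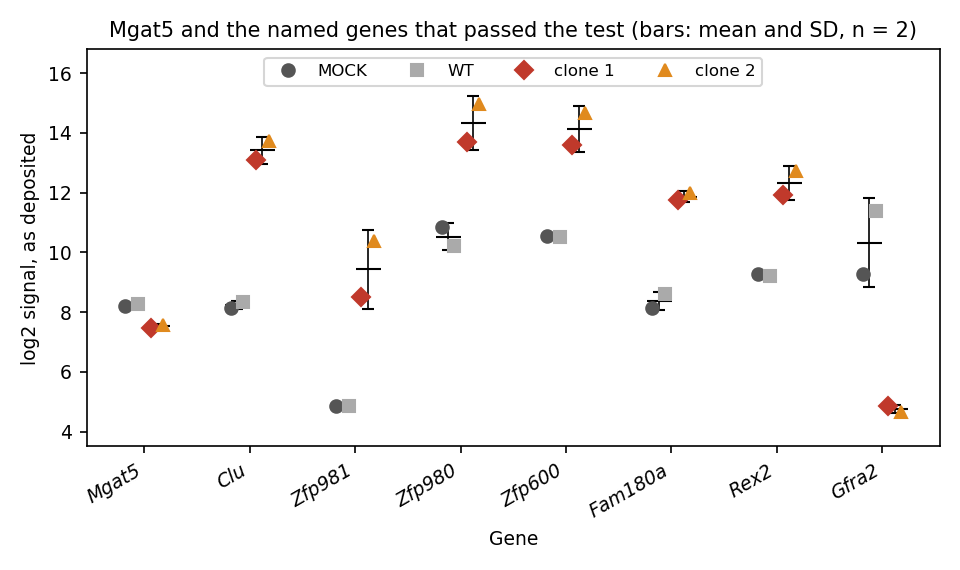
The log2 signal as deposited (vertical axis) of Mgat5 and of the 7 named genes that passed the limma test (horizontal axis), with 1 point per array and black bars for the mean and SD of each group (n = 2). Clu stood at 8.14 and 8.33 in the controls and at 13.09 and 13.73 in the clones, and Mgat5 at 7.46 and 7.57 in the clones, below both controls.

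The called zinc finger genes were not alone in their stretch of chromosome 4. Of the 13 measured genes between Smarca5-ps and Miip, chosen after their values were seen, 10 were higher in both clones than in both controls, with a median difference of 2.97 log2 units over all 13 and of 2.60 after quantile normalization. Zfp979 stood at 12.10 and 11.00 in the controls and at 14.03 and 15.58 in the clones, and Zfp985 at 9.80 and 9.94 against 11.56 and 13.29. Gm13238, Gm13034 and Zfp933 in the same stretch differed by -0.08, -0.20 and 0.01, and by -0.52, -0.59 and -0.40 after quantile normalization. The genes belong to a family of close copies, and no probe sequences were at hand to tell their signals apart.

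**Figure D2:**
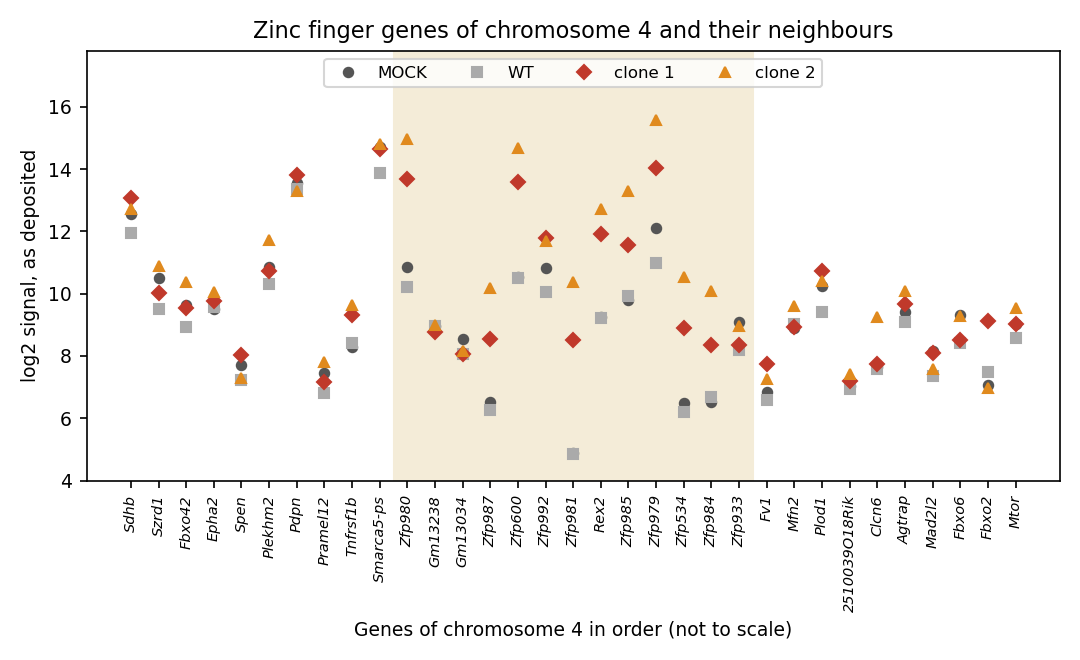
The log2 signal as deposited (vertical axis) of the 13 genes between Smarca5-ps and Miip (shaded) and of the 20 nearest genes around them with a mean signal above 7 (horizontal axis, in chromosome order, not to scale), 1 point per array. In the shaded stretch 10 of the 13 genes lay higher in both clones than in both controls, and the 20 flanking genes had a median difference of 0.47 log2 units, or 0.05 after quantile normalization.

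Genes with the widest gaps between the groups that did not pass the test are given as values. Rspo3, which encodes a secreted amplifier of Wnt signalling, stood at 5.16 and 5.01 in MOCK and WT and at 9.26 and 7.75 in clone 1 and clone 2 (limma adjusted p = 0.0523). Rgs2, a regulator of G protein signalling, was 6.29-fold higher (adjusted p = 0.0523), Abcg2, a drug efflux transporter, 5.87-fold (adjusted p = 0.0544), Car6, a secreted carbonic anhydrase, 9.77-fold (adjusted p = 0.0523), and Zfp534 10.3-fold. Etl4 stood at 3.14 and 4.19 in MOCK and WT and at 6.60 and 7.59 in clone 1 and clone 2. In the other direction, Ikzf2, a zinc finger transcription factor, stood at 8.45 and 8.23 in MOCK and WT and at 6.16 and 5.84 in clone 1 and clone 2 (5.07-fold lower, adjusted p = 0.0717), Sema5a, a semaphorin, was 4.80-fold lower (adjusted p = 0.0808), and Dcn, which encodes the matrix proteoglycan decorin, 9.34-fold lower (adjusted p = 0.121). Fam110c was 3.91-fold lower. Lilrb4a stood at 4.46 and 4.67 in clone 1 and clone 2, Prxl2a at 4.31 and 4.37, Ribc1 at 4.22 and 4.22, and Rab9b at 4.78 and 4.90, all below the median of the negative controls, and Opn5, Olfr1335 and Pou4f1 had signals of 5.29 or less on every array. At an adjusted p under 0.1 limma called 52 probe sets, 49 higher and 3 lower, and after quantile normalization 1, which was higher. At an unadjusted p under 0.05 it found 1944, of which 1674 were higher, where 1110 were to be expected by chance. That share of 86.1% higher became 52.7% after quantile normalization.

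The genes of N-glycan branching and trimming went both ways. Of the 16 measured, Mgat5 among them, 8 were higher and 8 lower in the knockout, and 0 passed over all genes or adjusted over the list alone (limma camera adjusted p = 0.695, direction down, with a median of -0.03 and a mean of 0.14). Man1c1, a trimming mannosidase, differed by 0.99 log2 units (SE 0.39) and Mogs, the glucosidase that starts trimming, by 0.89 (SE 0.38). Of 37 genes of glycan extension and capping 27 were higher, 0 passed over all genes and 4 passed adjusted over the list alone (camera adjusted p = 0.284). Those 4 were Gcnt1, which starts core 2 branches of O-glycans, at 1.96 log2 units (SE 0.40), the galactosyltransferase B4galt1 at 1.71 (SE 0.41), and the sialyltransferases St3gal6 at 1.48 (SE 0.40) and St3gal1. St3gal1 stood at 4.67 in MOCK and 4.56 in WT, below the median of the negative controls, and at 6.10 in clone 1 and 5.86 in clone 2. B4galt1 lies next to a segment of chromosome 4 whose genes were higher in both clones. Of 9 galectins 7 were higher and 0 passed either way (camera adjusted p = 0.319), with Lgals3 at 1.20 log2 units (SE 0.40).

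The sugar-supply and oligosaccharide lists rose relative to other genes, calls that were both lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). Here and for the lists below, that repeat is coarse with 4 arrays once adjusted, but 0 of 37 lists had an unadjusted p under 0.05 either. Simulated lists of independent genes shifted by 0.5 log2 units reached that in 15 of 20 runs. The estimated correlations of the called lists ran from 0.218 to 0.832, against the preset 0.01, and fry called 0 lists as well. The list calls therefore rest on the preset correlation, and whether the lists shifted stays open. Of 17 genes of hexosamine and nucleotide sugar supply 16 were higher (limma camera adjusted p = 0.0105), 0 passed over all genes and 3 adjusted over the list alone, namely Gne and Nans, which make sialic acid, at 1.87 (SE 0.42) and 1.71 log2 units (SE 0.43), and Gnpnat1 of the hexosamine pathway at 2.37-fold higher (SE 0.37 log2 units). Of 26 genes of the oligosaccharyltransferase and dolichol pathway 24 were higher (camera adjusted p = 0.0105), 0 passed over all genes and 1, the mannosyltransferase Alg2, adjusted over the list alone, at 1.66 log2 units (SE 0.38). After quantile normalization the camera adjusted p values were 0.272 and 0.368, within ranges over the alternatives of 0.0164 to 0.943 and 0.000175 to 0.943, and Gne, Nans and Alg2 lie in a segment of chromosome 4 whose genes were higher in both clones, without which the hexosamine list had an adjusted p of 0.134 and the dolichol list kept its call at 0.0418. The hexosamine call was lost without clone 2 (adjusted p = 0.143), and the dolichol call without clone 1 (0.174) or without WT (0.28).

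All 23 measured genes of the unfolded protein response were higher in the knockout, and the list rose (limma camera adjusted p = 9.19e-08), with a median difference of 0.88 log2 units, or 0.50 after quantile normalization. The call was lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). Its median was higher in each clone, by 1.04 log2 units in clone 1 and 0.84 in clone 2, at percentiles 100 and 99.8 of random lists matched on signal, and by 0.63 and 0.46 after quantile normalization. For MOCK minus WT the same list stood at percentile 0.71, or 10.3 after quantile normalization. An extreme percentile alone therefore does not set a clone apart. None passed over all genes, a count of 0, and 4 passed adjusted over the list alone. They were Chac1, a glutathione-degrading enzyme induced by this response, at 2.76 log2 units (SE 0.47), Ppp1r15a, a phosphatase subunit that restores translation, with controls below the median of the negative controls (4.25 in MOCK, 3.91 in WT, 5.37 in clone 1 and 7.12 in clone 2), Herpud1, part of the degradation machinery of the endoplasmic reticulum, at 1.83 (SE 0.45), and, outside the naming rule and chosen after its value was seen, the stress transcription factor Ddit3 at 2.83-fold higher (SE 0.44 log2 units). Sdf2l1 was 11.79 in clone 1 and 8.70 in clone 2, beside 7.96 in MOCK and 8.71 in WT. The call held after quantile normalization (camera adjusted p = 1.18e-05) and with each array left out in turn, with adjusted p from 7.69e-11 to 0.943 over the alternatives.

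Interferon response genes rose as a list, by a median of 1.62 log2 units with all 36 measured genes higher (limma camera adjusted p = 1.46e-12), a call that was lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). The list median was 3.15 log2 units above the controls in clone 2 and 0.23 in clone 1, at percentiles 100 and 33.1 of matched random lists. Rsad2, an antiviral enzyme, stood at 7.85 in MOCK, 7.06 in WT, 8.77 in clone 1 and 12.43 in clone 2, Oasl1 at 4.64, 4.12, 5.57 and 10.71, and the chemokine Cxcl10 at 13.65, 12.58, 14.49 and 17.08. Cxcl11, another chemokine, stood at 3.37 in MOCK, 3.59 in clone 1 and 9.55 in clone 2. After quantile normalization the list median was -0.04 in clone 1 and 2.70 in clone 2. The count past the test was 0 over all genes and 1 adjusted over the list alone, Ddx58, which senses viral RNA, at 2.36 log2 units (SE 0.50, chosen after its value was seen). All 19 genes of MHC class I antigen presentation were higher and the list rose (camera adjusted p = 1.29e-05), a call that was lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). Its median was 0.51 log2 units above the controls in clone 1, or 0.10 after quantile normalization, and clone 2 stood 1.49 above clone 1, or 1.34. H2-D1 stood at 13.30, 12.34, 13.75 and 15.47 in MOCK, WT, clone 1 and clone 2, and the peptide transporter subunit Tap1 at 11.33, 10.96, 11.66 and 13.88. In this list 0 members passed over all genes and 0 adjusted over the list alone. Without clone 2 neither list was called (adjusted p = 0.197 and 0.143, in ranges over the alternatives of 6.13e-76 to 0.943 and 2.21e-12 to 0.943).

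**Figure D3:**
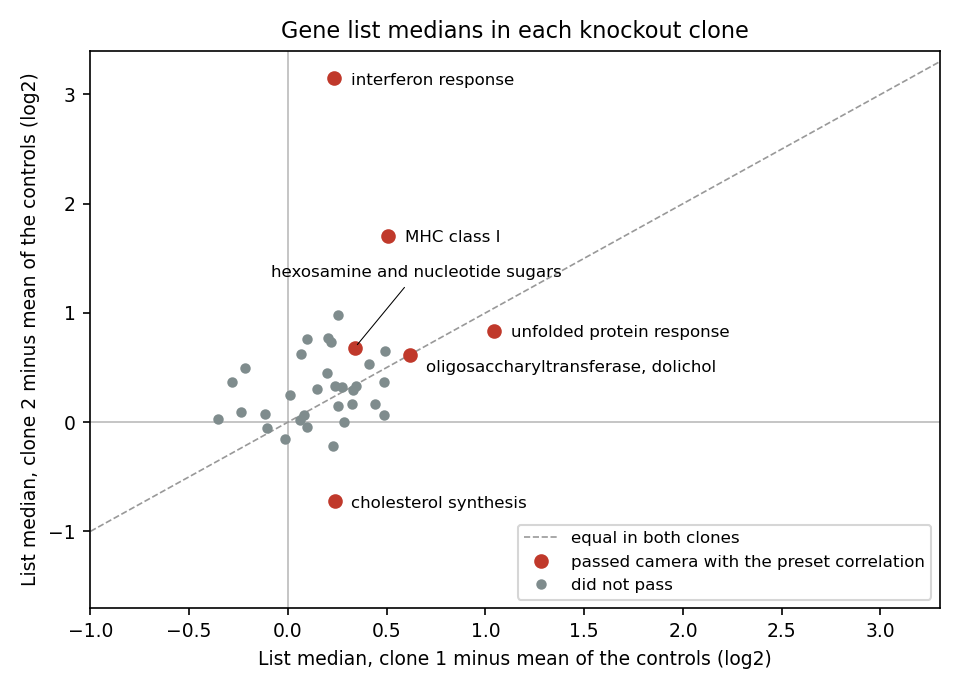
The median difference of each of the 37 gene lists from the mean of the controls in log2 units, in clone 1 (horizontal axis) and clone 2 (vertical axis), 1 point per list, red where limma's camera passed at its preset correlation. The interferon response stood at 0.23 in clone 1 and 3.15 in clone 2, the unfolded protein response at 1.04 and 0.84, and cholesterol synthesis at 0.24 and -0.73, where quantile normalization put the interferon response in clone 1 at -0.04 and cholesterol synthesis in clone 1 at -0.28.

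Other immune lists did not pass. Among 37 chemokines and cytokines 26 were higher (limma camera adjusted p = 0.326), 0 passed over all genes and 5 adjusted over the list alone, among them Ccl5 at 2.80 log2 units (SE 0.78), Ccl7 at 1.58 (SE 0.45) and, chosen after its value was seen, Tgfb2 at 1.37 (SE 0.41). The others, with controls below the median of the negative controls, were Cx3cl1, at 4.27 in MOCK, 4.47 in WT, 5.62 in clone 1 and 7.26 in clone 2, and, chosen after its value was seen, Il23a at 3.29, 3.58, 4.46 and 5.12. The checkpoint and NK ligand list, with 17 of 23 higher, had an adjusted p of 0.448, and its top member Cd274, which encodes PD-L1, stood at 6.63 in MOCK, 6.08 in WT, 6.36 in clone 1 and 9.52 in clone 2. NF-kB targets, with 18 of 22 higher, had an adjusted p of 0.23. In the checkpoint and NF-kB lists 0 members passed over all genes and 0 adjusted over the list alone. Without clone 1 the chemokine and NF-kB lists were called higher (adjusted p = 0.000414 and 0.00348).

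Cholesterol synthesis genes fell relative to other genes (limma camera adjusted p = 0.0105), with 12 of 19 lower and a median of -0.12 log2 units, or -0.61 after quantile normalization. The call was lost with an estimated correlation (adjusted p = 0.943 with an estimated correlation). The list median was -0.73 in clone 2 and 0.24 in clone 1, and after quantile normalization -1.21 in clone 2 and -0.28 in clone 1. The latter stood at percentile 1.01 of matched random lists. MOCK minus WT stood at -0.33 and percentile 0.05 on the same values, so the clone 1 value is no larger than the difference between the controls. In this list 0 members passed over all genes or adjusted over the list alone. Nsdhl, a demethylating enzyme of the pathway, stood at 14.32 in MOCK, 13.63 in WT, 13.59 in clone 1 and 11.69 in clone 2, and Fdps, which makes farnesyl diphosphate, at 11.94, 11.53, 11.71 and 10.13. Without clone 2 the list was not called and pointed up as deposited (adjusted p = 0.428) and down after quantile normalization (0.832), in a range over the alternatives of 2.93e-09 to 0.943. Hypoxia and glycolysis genes, with 15 of 28 lower, did not pass as deposited (camera adjusted p = 0.0907) or with fry (adjusted p = 0.945). Camera called them lower after quantile normalization (adjusted p = 0.0048) and with the filter at the median of mean signal (0.00107). With an array left out they were called without clone 1 or without WT, and not without clone 2 or without MOCK. The list median was -0.02 in clone 1 and -0.16 in clone 2, or -0.29 and -0.56 after quantile normalization. The call after quantile normalization was lost with an estimated correlation (adjusted p = 0.832 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, stood at -1.91 log2 units (SE 0.76), Pfkl, a glycolytic kinase, at -1.16 (SE 0.42), and Ndrg1 at 1.83 (SE 0.46). Fatty acid synthesis and storage genes, with 11 of 18 higher, had a camera adjusted p of 0.979, with a direction of down and a median of 0.10, or -0.29 after quantile normalization. In these lists as well 0 members passed over all genes or adjusted over the list alone.

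Growth and stress lists did not pass. The adjusted camera p of limma was 0.562 for mitosis (23 of 24 higher), 0.448 for DNA replication (23 of 27), 0.652 for p53 targets (14 of 22), 0.331 for NRF2 and oxidative stress (15 of 22), 0.101 for heat shock proteins (10 of 11), 0.963 for immediate early genes (10 of 16) and 0.252 for replication-dependent histones (17 of 19). Without MOCK, camera called mitosis (0.00182), DNA replication (0.0164), NRF2 (0.0293), heat shock (0.0162) and histones (0.0363) higher, and without clone 2 histones (0.00322). After quantile normalization the medians of mitosis, DNA replication, p53 targets and immediate early genes turned to -0.11, -0.11, -0.09 and -0.19. Of each, 0 members passed over all genes. Adjusted over the list alone, 1 member passed among the p53 targets, the cell cycle inhibitor Cdkn1a, which was 10.52 in MOCK, 10.09 in WT, 12.57 in clone 1 and 12.99 in clone 2. In the NRF2 list 1 member passed in that way, Nqo1, a quinone reductase, at 2.68 log2 units (SE 0.57), and among immediate early genes 1, the transcription factor Egr2, at 2.12 (SE 0.47), in a list whose camera direction was down.

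Adhesion, matrix and signalling lists did not pass either. The limma camera adjusted p was 0.15 for epithelial genes (17 of 31 higher, median level 4.43 or less on every array), 0.23 for mesenchymal genes (19 of 24), 0.326 for integrins and cell adhesion (24 of 29), 0.448 for extracellular matrix and remodelling (28 of 40), 0.88 for mucins and proteoglycans (13 of 22), 0.239 for receptor kinases and cytokine receptors (23 of 30), 0.151 for TGF-beta targets (16 of 19), 0.205 for MAPK targets (8 of 20) and 0.963 for Wnt targets (13 of 16, camera direction down). Without clone 1 the mesenchymal and TGF-beta lists were called higher (0.0371 and 0.000238), and without MOCK the epithelial list was called lower (0.0164). The median of epithelial genes was 0.03 as deposited with a mean of -0.01, and -0.10 after quantile normalization, where receptor kinases stood at -0.03. With the filter at the median of mean signal, MAPK targets were called lower (0.0472; median -0.17, mean 0.00) and mucins and proteoglycans higher (0.025). In each, 0 members passed over all genes. Adjusted over the list alone, 3 matrix genes passed, namely Dcn at -3.22 log2 units (SE 0.63), Plat, the tissue plasminogen activator, at 4.96 in MOCK, 5.69 in WT, 7.18 in clone 1 and 8.51 in clone 2, and Bgn, which encodes the proteoglycan biglycan, at 1.59 log2 units (SE 0.38, chosen after its value was seen), and 1 proteoglycan gene, Ext1, which elongates heparan sulfate, at 1.52 log2 units (SE 0.37).

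The medians of the immune cell markers lay below those of the negative controls. The median level was 4.10 log2 units or less on every array for macrophage and myeloid markers and 4.09 or less for T and NK cell markers, with limma camera adjusted p values of 0.101 and 0.319. Endothelial and muscle markers had adjusted p values of 0.0503 and 0.963, and fibroblast markers 0.789, and without MOCK the endothelial list was called lower (0.00711). Camera pointed down for T and NK cell, muscle and fibroblast markers, whose medians were 0.17, 0.07 and -0.04 and whose means were 0.01, 0.20 and 0.17. After quantile normalization it pointed down for T and NK cell markers and up for muscle and fibroblast markers, with medians of 0.09, -0.07 and -0.05. Of these 5 lists 0 members passed over all genes, and adjusted over the list alone 3 fibroblast markers did, Dcn, Scara5 at 2.75 log2 units (SE 0.69) and Ogn, a matrix proteoglycan, at 1.80 (SE 0.37). Ogn had signals from 14.60 to 16.49, Dcn from 8.94 to 13.61 and the endothelial marker Flt1 from 6.75 to 9.51. Cytosolic ribosomal proteins, with all 22 higher, and housekeeping genes, with 8 of 12 higher, had adjusted p values of 0.278 and 0.963, medians of 0.04 and -0.01 after quantile normalization and, for ribosomal proteins, a call without MOCK (4.05e-05). Their median levels were lowest in WT, at 15.12 and 15.73 against 16.14 or more and 16.41 or more on the other arrays.

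The clones differed from each other at more probe sets than the controls did. Clone 2 and clone 1 were at least 1 log2 unit apart at 2823 probe sets, with 1909 higher and 914 lower in clone 2, and each clone is a single array, so no test was made. Thbs2, which encodes a matrix glycoprotein that inhibits angiogenesis, stood at 4.28 in clone 1 and 13.55 in clone 2, beside 11.50 in MOCK and 12.51 in WT, so clone 1 was the array that stood apart. Tex101 stood at 5.52 in clone 1 and 13.48 in clone 2, the transcription factor Ebf1 at 5.48 and 12.46, Pon3 at 4.51 and 10.60, Cxcl11 at 3.59 and 9.55, and Dppa2, a gene of pluripotent cells, at 7.34 and 13.13. In the other direction, Igf2, the insulin-like growth factor, stood at 13.83 in clone 1 and 6.28 in clone 2, beside 10.10 in MOCK and 8.19 in WT, the matrix protease Mmp3 at 10.03 and 3.59, Trp53i11 at 10.25 and 4.20, Lpar4, a receptor for lysophosphatidic acid, at 10.11 and 4.39, Cavin2 at 11.15 and 5.87, and Hcfc1r1 at 9.18 and 3.95. After quantile normalization the number was 2504, with 1230 higher and 1274 lower in clone 2.

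MOCK and WT were at least 1 log2 unit apart at 2232 probe sets, with 1951 higher in MOCK and 281 lower, again with no test. Cox6a2 was 6.23-fold higher in MOCK and Plscr2 5.72-fold. The growth factor gene Pdgfc stood at 7.17 in MOCK and 4.73 in WT, and Anxa6 at 7.02 and 4.61, where WT lay below the median of the negative controls. Tgfbi, a matrix protein induced by TGF-beta, was 5.34-fold lower in MOCK, Slc52a3, a riboflavin transporter, 5.06-fold, Gfra2 4.34-fold and Sgsm1 4.24-fold, and Foxp2 stood at 4.23 in MOCK and 6.43 in WT. Lipf at 5.24 and 2.31, Vmn2r13 at 5.56 and 3.22 and Rcan2 at 2.61 and 4.85 in MOCK and WT lay near or below the median of the negative controls on both arrays, so their differences say little about expression. After quantile normalization the number was 1004, with 411 higher and 593 lower in MOCK.

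Both clones lay at least 1 log2 unit clear of both controls at 337 probe sets, 304 higher and 33 lower. The other ways to pair the 4 arrays gave 47 and 69, and limma called 0 probe sets in each of them, with 409 and 766 at an unadjusted p under 0.05. In those pairings each group mixes a clone with a control, so differences between clones and controls add to the spread within groups. Their lower counts are therefore no measure of chance. After quantile normalization the knockout count was 231, with 173 higher and 58 lower, against 43 and 57. With 1 array left out the knockout count was 672 without WT, 1038 without clone 2, 1680 without MOCK and 1842 without clone 1. The groups did not overlap at 39.5% of all probe sets, where chance gives 33.3%.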

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

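The combinations of settings and the lists without the genes from Chmp5 to Alg2 were chosen after the data were seen. From 9 called probe sets, the number went to 1 with quantile normalization, 196 and 125 with the filters at the median and the 25th percentile, 340 with trend and robust, 0 without moderation, 23 with 1 probe set per gene, 52 at an adjusted p under 0.1, 1412 with an unadjusted p under 0.05 and 2-fold, 925 with that threshold after quantile normalization, and 0 with quantile normalization without WT. At the counts of 0, limma had 1423 and 855 probe sets at an unadjusted p under 0.05. With each array left out it ran from 0 without WT, and 1 without MOCK, to 149 without clone 2 and 529 without clone 1. All 9 were among those called with either filter. Clu kept its call in 8 of 11 alternatives, with adjusted p from 5.65e-19 to 0.713. The cause was not tested for these counts. The share of higher probe sets at an unadjusted p under 0.05 was 73.9% without WT, 74.0% without clone 2, 86.3% without clone 1 and 92.3% without MOCK. The 4 hybridisation controls were 0.50 log2 units higher on WT than on the other arrays, while 4594 probe sets of like brightness were -0.64.

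From 6 called lists, the number went to 0 with an estimated correlation, 0 with fry and 0 with quantile normalization and an estimated correlation, with 0, 1 and 1 lists at an unadjusted p under 0.05, to 1 with quantile normalization without clone 2, and from 3 without clone 2 to 14 without MOCK. The cholesterol list reversed without clone 2 as deposited, with p signed by direction from -0.0137 to 0.266 over the arrays left out, and without clone 2 after quantile normalization it still pointed down (-0.361). Mgat5 stayed lower and uncalled in all alternatives run, from -1.11 to -0.66 log2 units. The difference between the clones moved to 1804 with the filter at the median. That filter keeps 11103 of 22206 probe sets, so it lowers a count by construction. The difference between the controls moved to 1004 with quantile normalization. The gap count of 337 moved to 1369 at 1.5-fold and to between 672 and 1842 with an array left out, where fewer arrays widen a gap by construction. Of 1792 values of 167 named genes under an alternative, 1585 kept direction and call, 164 gained a call, 26 lost it, 17 uncalled ones changed sign and 0 called ones reversed. No paired analysis was possible because the numbers of the controls are only the order of deposit. The 3 ways to pair the 4 arrays are too few for a share under 0.05. The real split had 9 called and the others, whose groups each mix a clone with a control, at most 0.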

Other observations

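The tests of explanations given here were all chosen after the values were seen. The 16 genes measured between Gm4907 and Btbd35f29 on chromosome X, among them Slx and chosen after their values were seen, were higher in both clones than in both controls at all 16 members, with a median of 2.20 log2 units as deposited and 1.87 after quantile normalization. Slx stood at 6.20 in MOCK, 6.38 in WT, 7.75 in clone 1 and 8.94 in clone 2, and Gm5168 at 7.88, 6.95, 10.27 and 10.17. On quantile values the medians of clone 1 and clone 2 stood 2.15 and 1.76 above the controls. Gm10147 and Gm10487 had equal values on every array to 2 decimals, so the 16 genes are not 16 separate measurements.

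Blocks of neighbouring genes were shifted together in single arrays. Among 7877 genes with a mean signal above 7, 13 separate blocks of 41 neighbours had a median difference between clone 1 and the controls beyond the highest of 1000 shuffled gene orders, 8 did for clone 2 and 6 for MOCK minus WT, on quantile values. In clone 1 the block from Flrt2 to Cdc42bpb on chromosome 12 had a median of -0.93 and that from Tsc22d1 to Ggact on chromosome 14 -0.86. In clone 2 the block from Prrg1 to Sh3bgrl on chromosome X had a median of -0.95 and that from Ect2 to D3Ertd751e on chromosome 3 -0.78. In MOCK minus WT the block from Sec24c to Sh3bp5 on chromosome 14 had -0.72. MOCK and WT held exactly the same value at 60 features and no other pair of arrays did at any. For that pair 145 of the dimmer features had unequal values within 0.005 of each other. Spread evenly over the steps in which values are given, these lead to 0.145 exact matches.

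The block from Chmp5 to Alg2 on chromosome 4, which holds Gne, Nans and Tgfbr1, was higher in both clones, with medians over its 41 genes of 1.19 log2 units in clone 1 and 0.67 in clone 2 on quantile values, and -0.04 for MOCK minus WT. It was picked as the block with the largest shift in clone 1, so its clone 1 median is high by selection. The chromosome 4 blocks of clone 2 had other bounds, from Ube2j1 to Gne (median 0.72) and from Tdrd7 to Pole3 (0.75). The narrower range of the WT array is argued against by a median of 0.94 against MOCK alone. A chance coincidence of blocks stays open, since with clone 2 moved along the genome against clone 1, each against its own control, 12.9% of 6996 shifts held a window as high in both clones with clone 1 against MOCK, and 1.4% with clone 1 against WT. More copies of the segment in both clones may account for it, and 85.4% of its genes were higher in both, but with no DNA measurement that cannot be told apart from a change in regulation. That share comes from the window picked on clone 1, so it is no separate support. An effect of Mgat5 loss, and a shared origin of the clones before the knockout, stay open as untested.

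The zinc finger genes of chromosome 4 were higher in both clones at 10 of 13 genes, with a median of 2.60 over all 13 on quantile values. A gain of the segment that reaches the flanking genes is argued against by their median of 0.051 (20 genes), and the narrower range of the WT array by a median of 2.57 for the knockout minus MOCK. Signal shared between near-identical family members could account for part of the pattern, but without probe sequences the members cannot be told apart, and of the 3 genes that were not higher, 1 lay within 0.5 of 0 on quantile values (Zfp933 at -0.40) beside Gm13238 at -0.52 and Gm13034 at -0.59. A gain of the stretch alone, and a loss of silencing of the family in the clones through Mgat5 loss or through cloning, stay open as untested.

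Interferon genes were higher in clone 2, by a median of 2.70 over 36 genes on quantile values, with 34 of them at least 1 log2 unit up. The narrower range of the WT array is argued against by a median of 2.79 for clone 2 minus clone 1. Immune cells as a large share of the culture are argued against by a median of 0.11 over the 32 genes of the myeloid and the T and NK lists, with Ptprc at 4.77, Tyrobp at 3.51, Cd14 at 7.08 and Lyz2 at 5.92 in clone 2. Of the 32, 18 were higher in clone 2, and 1 by at least 1 log2 unit, Cd8a, at 5.27 beside 4.1 in MOCK and 4.01 in WT. A median over several cell types with signals near background cannot show a few cells of 1 type, so a small admixture stays open. An effect common to both knockout clones is argued against for the list as a whole by the clone 1 median of -0.038, but 4 of the 36 genes were at least 1 log2 unit up in clone 1, so a shared rise of part of the list stays open. A candidate explanation for the rest is an event of clone 2 or its culture, which a single array of that clone leaves untested.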
